A study of Arabidopsis thaliana with 60 samples.

How the data were processed

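RNA from stems of Arabidopsis thaliana was measured by RNA sequencing in 5 groups of 3 samples: the wild type Col-0 (set 1), the HCT-RNAi line and the gpt2-1 line, called trial 1 here, and a second set of Col-0 (set 2) with the 35S GPT2 line, called trial 2. Per the labels, plants grew for 9 to 10 weeks in 0.5x Noren medium, RNA came from a column kit for plant tissue, and libraries were made with a TruSeq stranded mRNA kit, which marks the strand of each read. The 60 sequencing records form 15 samples with 4 records each, and the 4 records of a sample shared 1 deposited table, so they were counted as 1 sample. The labels speak of biological replicates and do not say how many plants each one pooled.

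The authors deposited raw counts of reads per gene, whole numbers with a different total in each table. STAR, DESeq2 and the TAIR10 genome are named in the submitters' processing notes, without a role. The counting tool, its strand setting and the gene annotation are not given in the sources used here. Each table held 38186 rows, of which 219 without a gene name were left out (between 0.000322% and 0.00117% of the counts). All of the 37967 remaining locus identifiers matched a gene table of assembly TAIR10.1, from which gene symbols, coordinates and exons were taken. Total counts per sample were 16591700 to 24150608 in Col-0 set 1, 23041771 to 26129812 in HCT-RNAi, 21352999 to 22618598 in gpt2-1, 5258309, 14603171 and 31713084 in Col-0 set 2, and 11481919, 3827816 and 12536593 in 35S GPT2. No pair of replicates agreed within sampling noise: chi-square per degree of freedom over genes with a summed count of at least 20 was 1.95 to 33.4 in the 15 pairs.

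In 5 of the deposited tables, all 3 of Col-0 set 2 and replicates 2 and 3 of 35S GPT2, the counts did not follow their gene labels. Across genes, their Spearman correlation with the first Col-0 set 1 sample was 0.101 to 0.112 as labelled. The first 35S GPT2 table lists its genes in another order, and reading the counts of the 5 tables in that order gave 0.884 to 0.925. Against the first 35S GPT2 sample, the lowest correlation in any full window of 1000 rows was then 0.841, and shifting the order by 1 row gave at most 0.247. All trial 2 results use the counts read in that order. This was chosen after seeing the data and rests on the row order of a sibling table, and results with the labels as deposited are an added alternative. As deposited, the row labelled GPT2 held 34, 29 and 25 counts in Col-0 set 2, the same 3 values as in Col-0 set 1. This was the only such row of the 17302 with at least 20 counts in every Col-0 set 1 sample. The place of these values in the other order falls on PGD1 (AT1G64190), which was therefore left out of the trial 2 fits.

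A second check compared the trial 1 tables at overlapping genes. Genes whose exons lie under exons of the opposite strand had far lower counts in Col-0 set 1 and gpt2-1 than in HCT-RNAi and trial 2 (values in the report). For HCT-RNAi, counts of genes are therefore given also for the 14448 tested genes without an exon base shared with an opposite-strand exon, and the largest changes were named again among them. List tests were repeated on these genes in each comparison that had them. These repeats were added after seeing the data. Counts of genes that share reads with a near-identical copy, such as LHCB1.1 to LHCB1.5, depend on how the authors' counting split those reads.

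Groups were compared with edgeR (version 4.0.16, with R 4.3.3 and limma 3.58.1): its quasi-likelihood F test on raw counts with TMM scaling, filterByExpr, and Benjamini-Hochberg adjustment, at an adjusted p under 0.05 and with no fold minimum. The 9 trial 1 samples shared 1 fit and the 6 trial 2 samples another. HCT-RNAi and gpt2-1 were each compared with Col-0 set 1 and with each other, and 35S GPT2 with Col-0 set 2. The difference between the effects of 35S GPT2 and gpt2-1 was tested in 1 fit of all 15 samples, and the Col-0 sets were compared in a fit of their own. Fold changes are log2 with their standard error (SE), and levels are TMM-scaled CPM, that is counts per gene relative to the library's total (mean ± SD, n = 3), unless said otherwise. There were 28 gene lists with 428 loci, tested by camera with a preset correlation of 0.01 where at least 4 members were tested, and adjusted over the 80 tests of the 3 main comparisons (over 55 tests for the differences between lines). A repeat let camera estimate the correlation of each list, and fry gave a further one.

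GPT2 and HCT were reported first. By a rule set before the data were examined, the genes named were then the 8 largest rises and falls per comparison among genes that passed the test, had at least 5 CPM on average and did not overlap between groups, and up to 4 members with the smallest p of each list that camera called, or of the lists for monolignols, lignin polymerization, plastid translocators, starch and the pentose phosphate pathway in any case. The comparisons, lists and alternatives were likewise set before the data were examined, except where said otherwise. Not every gene taken by the naming rule is printed, but counts of named genes include them all. The alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter, an adjusted p under 0.01, an absolute log2 fold change of at least 1, all samples in 1 fit, only the compared groups, the sample number as a block, and leaving out each sample in turn.

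In trial 2, samples with the same number deviated together from their group means (correlations across genes of 0.22, 0.39 and 0.47), so the number, which comes from the sample titles, was taken to pair Col-0 set 2 with 35S GPT2. Values with this block are given beside a result where they change it.

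On simulated counts made from these samples, with 200 genes changed, the share of changed genes recovered at an absolute log2 change of 1 was 92% for HCT-RNAi, 87% for gpt2-1 and 41% for 35S GPT2, and at 2 it was 94%, 90% and 80%. Beside the recovered genes of both sizes, 24, 9 and 10 unchanged genes passed the test, of 19199, 19209 and 17980 tested genes. The biological coefficient of variation was 0.0402 in trial 1 and 0.234 in trial 2. P-values measure only the spread between these samples. Lines were tested only against the wild type of their own trial, since trial and line cannot be told apart otherwise, and levels in Col-0 set 2 stand beside some trial 1 values as a description. The HCT-RNAi tables also differed from those of Col-0 set 1 in ways that Col-0 set 2 shares (values in the report). An effect of HCT silencing is thus not fully set apart from a difference between tables.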

Results

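Stem transcriptomes were compared between wild type Arabidopsis and lines with altered HCT or GPT2, to ask how expression of the plastid translocator GPT2 relates to lignin synthesis. HCT-RNAi plants carry a silencing construct against HCT, gpt2-1 is a mutant line of GPT2, and 35S GPT2 expresses GPT2 from the strong 35S promoter. Each of the 5 groups had 3 samples, with total counts of 3827816 to 31713084 per sample.

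HCT (AT5G48930) encodes a hydroxycinnamoyl transferase of the lignin pathway and lies on chromosome 5, 19836299 to 19838235, on the minus strand of TAIR10.1, with 2 exons. Without TMM scaling, HCT stood at 382 ± 19.6 CPM (SD, n = 3) in Col-0 set 1, at 150 ± 7.73 CPM in HCT-RNAi and at 291 ± 11.4 CPM in the libraries labelled gpt2-1. In trial 2 it stood at 486 ± 32.1 CPM in Col-0 set 2 and 693 ± 162 CPM in 35S GPT2. HCT fell in HCT-RNAi, with a log2 fold change of -1.34 (SE 0.05, edgeR adjusted p = 4.36e-19). In the libraries labelled gpt2-1 it fell by less, with a log2 fold change of -0.17 (SE 0.05, edgeR adjusted p = 0.00428) and TMM-scaled levels of 323 ± 12.5 against 362 ± 23.8 CPM. In 35S GPT2 its log2 fold change was 0.53 and did not pass the test (edgeR adjusted p = 0.21), but with the sample number as a block it was 0.51 and passed (edgeR adjusted p = 0.033).

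GPT2 (AT1G61800) encodes a glucose-6-phosphate/phosphate translocator of the plastid envelope and lies on chromosome 1, 22824414 to 22826902, on the plus strand, with 4 or 5 exons in its 2 annotated transcripts. Without TMM scaling, GPT2 stood at 1.399 ± 0.17 CPM (SD, n = 3) in Col-0 set 1 and at 8.48 ± 1.97 CPM in HCT-RNAi. The libraries labelled gpt2-1 held 115 ± 3.27 CPM, against their label, with every library above 112 CPM. In trial 2 GPT2 stood at 2.88 ± 3.11 CPM in Col-0 set 2 and 263 ± 43.0 CPM in 35S GPT2. The Col-0 set 2 libraries held 6.466 CPM in replicate 1 and 1.096 and 1.072 CPM in replicates 2 and 3. The log2 fold changes were 2.61 (SE 0.17) in HCT-RNAi, 6.59 (SE 0.11) in the libraries labelled gpt2-1 and 7.05 (SE 0.56) in 35S GPT2, and all 3 passed the test (edgeR adjusted p = 2.77e-13, 1.50e-25 and 0.000427). Without Col-0 set 2 replicate 1 the log2 fold change in 35S GPT2 was 7.95. Leaving out each sample in turn gave 6.45 to 7.95, each past the test in edgeR. Counts per gene do not show which part of the GPT2 transcript was read.

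**Figure D1:**
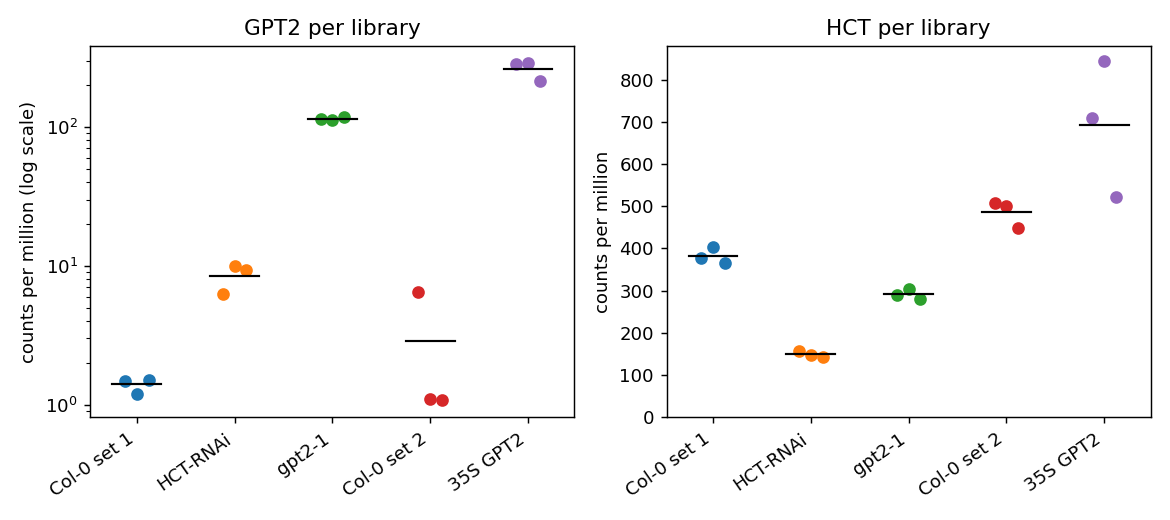
GPT2 (left, log axis) and HCT (right) in CPM without TMM scaling in each library, by group, with points for the 3 libraries and a bar for their mean. The 3 libraries labelled gpt2-1 lie between 112.6 and 118.7 CPM of GPT2, and those of Col-0 set 1 between 1.201 and 1.507 CPM. The 3 HCT-RNAi libraries have the lowest HCT levels, 143.1 to 158.2 CPM.

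Silencing of HCT was compared with wild type to ask what follows in the stem when a lignin enzyme is lowered. PAL4 (log2 fold change -1.09, SE 0.06, 245 ± 11.1 against 520 ± 52.3 CPM, n = 3) and C4H (-0.84, SE 0.04, 374 ± 16.3 against 667 ± 22.3 CPM), which encode entry enzymes of the phenylpropanoid pathway, fell. RAB18 (2.44, SE 0.06, 146 ± 5.19 against 26.8 ± 1.17 CPM), a dehydrin, COR15A (2.46, SE 0.08), KIN2 (1.44, SE 0.05) and the proline synthesis gene P5CS1 (1.89, SE 0.06), which respond to drought and cold, rose. BAM5 (2.61, SE 0.14), a beta-amylase, the phosphorylase PHS1 (0.96, SE 0.04) and SBE2.1 (0.94, SE 0.05), a starch branching enzyme, rose as well. Each of these genes passed the test in edgeR with Benjamini-Hochberg adjustment, and the largest adjusted p among them was 1.82e-15, for C4H.

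By list, 15 of 20 monolignol genes fell and 3 rose (camera adjusted p = 3.40e-05; adjusted p = 0.37 with an estimated correlation). HCT, which the construct targets, is among the 15 that fell, and no call of this list was tested without HCT. CCR1, a cinnamoyl-CoA reductase, was among those that rose (1.07, SE 0.04), but 77.2% of its exon bases lie under an opposite-strand exon. Of 11 drought, cold and ABA genes 8 rose and 2 fell (camera adjusted p = 1.08e-07; 0.028 with an estimated correlation). Of 15 starch synthesis genes 11 rose and 3 fell (camera adjusted p = 0.000275; adjusted p = 0.11 with an estimated correlation), with APL4 at 2.00, APL1 at 1.91 and ISA1 at 0.83. Of their exon bases 6.18%, 37.2% and 22.8% lie under an opposite-strand exon. Of 14 starch degradation genes 11 rose and 1 fell (camera adjusted p = 7.26e-05; adjusted p = 0.065 with an estimated correlation), DPE2 and PHS2 at 0.80 and 0.66. In the clock list 11 of 16 genes fell and 4 rose (camera adjusted p = 0.00325; adjusted p = 0.080 with an estimated correlation), with CCA1 at -0.96, PRR9 at -1.34, CDF1 at -1.21 and LHY at -0.68. Of 23 jasmonate and ethylene genes 14 rose and 2 fell (camera adjusted p = 2.63e-06; adjusted p = 0.048 with an estimated correlation), with the storage proteins VSP1 and VSP2 at 2.12 and 1.05 and AOC1 at 1.43. MYC2, with 98.5% of its exon bases under an opposite-strand exon, is among the 14 that rose. The photosynthesis list had 16 of 31 genes higher and 3 lower (camera adjusted p = 0.000799; adjusted p = 0.60 with an estimated correlation), among them GAPB (0.52), LHCB1.2 (0.51) and RBCS1A (0.38). LHCB1.5, with 100% overlap, is among its 16 higher genes. Of 7 epidermis markers 5 fell, including the wax genes CER6 (-0.69) and CER3 (-0.61) and FDH (-0.74), and PDF1 rose by 1.67 (camera adjusted p = 0.0488; adjusted p = 0.42 with an estimated correlation), with a median of -0.61 and a mean of 0.02. The counts of these 8 lists were the same when adjusted over the list alone. Of 10 splits of the HCT-RNAi and Col-0 set 1 samples, the real one included, 5 called at least as many lists.

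Lists not called by camera still held genes that changed in HCT-RNAi. Of 20 cellulose and xylan genes 6 rose and 8 fell (camera adjusted p = 0.37), or 10 fell adjusted over the list alone. Of 26 secondary wall transcription factors 7 rose and 11 fell (camera adjusted p = 0.51), and of 20 shikimate and phenylalanine genes 3 rose and 13 fell (camera adjusted p = 0.11). These were the same numbers as adjusted over the list alone. Of 14 laccases and peroxidases 4 rose and 3 fell (camera adjusted p = 0.61), with LAC17 at 0.81 (25.2% overlap with an opposite-strand exon), PRX71 at 0.88, PRX47 at 1.26 (5.56%) and PRX66 at 1.55 (9.43%). Of 10 plastid translocators 5 rose, with GPT2 first, PPT2 at 1.04 and MEX1 at 0.57, and NTT1 fell (-0.34, camera adjusted p = 0.46). Of 19 pentose phosphate genes 7 rose and 4 fell (camera adjusted p = 0.43), with PGD1 at 1.32 (35.05% overlap), PGL1 at 0.74 (6.23%), RPI3 at 0.73 (23.7%) and G6PD6 at -0.28. Adjusted over the list alone, the counts were the same for laccases and peroxidases and for the translocators, and 9 rose and 4 fell in the pentose phosphate list.

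Over all genes, 11167 of 20053 passed the test in HCT-RNAi, 5859 higher and 5308 lower, and 2058 of them changed at least 2-fold. Of the 1490 genes at least 2-fold higher, 1020 share exon bases with an exon of the opposite strand. The median log2 difference between HCT-RNAi and Col-0 set 1 was -0.05 for genes without opposite-strand overlap and 4.34 for genes with 75 to 100% of their exon bases under an opposite-strand exon, and in Col-0 set 2, also wild type, it was 4.49 at that overlap. For genes with 25 to 50% overlap it was 0.51 in HCT-RNAi, with 83.4% of them higher, and for those with 10 to 25% it was 0.15. LHCB1.5, a chlorophyll-binding protein with 100% overlap, had 5970 ± 223 CPM in HCT-RNAi, 0 counts in Col-0 set 1 and 5841 CPM without TMM scaling in Col-0 set 2, and the jasmonate regulator MYC2, with 98.5%, had 1424 ± 29.4 CPM against 0 counts. With 3 counts over the group as the floor, EXO70H7 was at least 5344-fold higher in HCT-RNAi, with 96.8% overlap. Unlike LHCB1.5, these genes stood lower in Col-0 set 2 than in HCT-RNAi. Without TMM scaling, Col-0 set 2 held 69.9 CPM of MYC2 and 41.2 CPM of EXO70H7, which had 252 CPM in HCT-RNAi. Trial and line cannot be told apart in this.

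Among genes without overlap, 3409 were higher and 4271 lower, with 470 and 435 at least 2-fold. Scaled and fitted on these genes alone, 3756 were higher and 3636 lower, so the excess of lower genes did not hold. The largest rises there were GRP9 (log2 fold change 8.81, SE 0.21, 156 ± 10.9 against 0.35 ± 0.23 CPM), a glycine-rich protein, ELIP1 (4.86, SE 0.16), an early light-inducible protein, AT2G37870 (3.32), AT4G01985 (3.28), MLP28 (3.03, SE 0.05) and AT5G22860 (2.66). The largest falls were led by the signal recognition particle RNA gene AT7SL-1 (-10.27, SE 0.18), AT4G15150 (-9.37) and AT3G05945 (-9.22). These genes were near 0 in Col-0 set 2 too. It held 0 CPM of AT7SL-1 and AT3G05945 and 0.06 CPM, without TMM scaling, of AT4G15150. Of 24 genes more than 20-fold lower in HCT-RNAi, with a median overlap of 0, 22 were as low in Col-0 set 2. Leaving out genes with overlap thus does not remove every difference between the tables that wild type shows too. An effect of the line and such a difference cannot be told apart on these genes. Whether such a difference also lies behind changes of other genes in HCT-RNAi was not tested. AT2G06045, with 0 counts in HCT-RNAi and 4.91 ± 0.28 CPM in Col-0 set 1, was at least 122-fold lower against that floor. Fitted on genes without overlap alone, 13 of 15 monolignol genes fell and 1 rose (camera adjusted p = 2.98e-10; adjusted p = 0.18 with an estimated correlation), 11 of 20 jasmonate and ethylene genes rose and 2 fell (camera adjusted p = 0.000331; adjusted p = 0.059 with an estimated correlation), and the lists for starch degradation, drought and clock were called with both correlations (0.024, 0.024 and 0.028 with an estimated correlation). In that fit, starch synthesis (6 of 9 higher, 2 lower), photosynthesis (13 of 21 higher, 1 lower) and epidermis markers (5 of 7 lower, 2 higher) were called again (camera adjusted p = 0.00592, 0.00897 and 0.0168; adjusted p = 0.18, 0.64 and 0.29 with an estimated correlation). Also called there were the lists for shikimate and phenylalanine (10 of 13 lower), salicylic acid (11 of 23 higher, 3 lower), plastid translocators (4 of 6 higher) and cambium (5 of 6 higher), which were not called over all genes (camera adjusted p = 0.00183, 0.00701, 0.0141 and 0.0104; adjusted p = 0.19, 0.22, 0.15 and 0.29 with an estimated correlation).

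**Figure D2:**
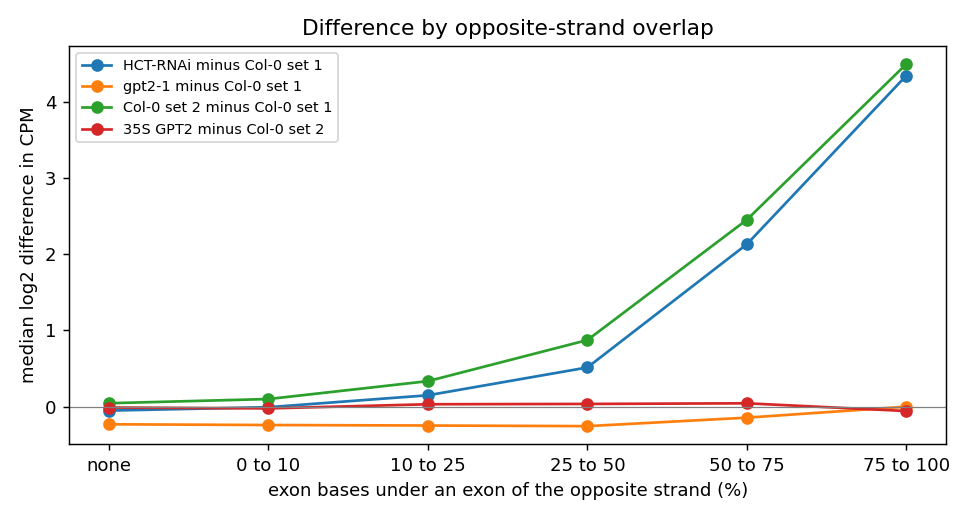
Median log2 difference in CPM between groups (vertical axis) for genes binned by the share of their exon bases that lie under an exon of the opposite strand (horizontal axis, percent), with 1 line per pair of groups. HCT-RNAi and Col-0 set 2 climb to 4.34 and 4.49 above Col-0 set 1 at 75 to 100%, and the libraries labelled gpt2-1 against Col-0 set 1 and 35S GPT2 against Col-0 set 2 stay between -0.25 and 0.04.

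The libraries labelled gpt2-1 were compared with the same wild type samples to ask what the GPT2 mutation changes, and every direction here belongs to libraries in which GPT2 was high. The jasmonate synthesis genes LOX3 (log2 fold change 1.81, SE 0.04, 1966 ± 37.6 against 561 ± 16.8 CPM, n = 3), LOX4 (1.80, SE 0.04) and OPR3 (2.06, SE 0.05) rose. WRKY18 (2.05, SE 0.05, 1070 ± 27.96 against 260 ± 15.9 CPM), a regulator of salicylic acid responses, rose as well. FRA8 (-0.93, SE 0.05) and IRX9 (-0.73, SE 0.05), both needed for xylan of secondary walls, fell. The clock output GRP7 (-2.92, SE 0.06, 42.4 ± 5.44 against 321 ± 14.2 CPM) and the clock gene PRR5 (-2.96, SE 0.08) were among the largest falls, while LHY rose (1.27, SE 0.05). All of these passed the test in edgeR, and over all genes 10677 of 20053 did, 5496 higher and 5181 lower, with 2033 at least 2-fold.

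By list, 20 of 23 jasmonate and ethylene genes rose and 1 fell (camera adjusted p = 6.52e-29; 0.00399 with an estimated correlation), with JAZ7 at 2.14. Of 27 salicylic acid genes 19 rose and 3 fell (camera adjusted p = 3.41e-08; adjusted p = 0.065 with an estimated correlation), with PR2 at 1.298, CBP60G at 0.99 and the salicylic acid synthesis gene ICS1 at 1.45. Of 16 glucosinolate genes 9 rose and 1 fell (camera adjusted p = 0.000737; adjusted p = 0.36 with an estimated correlation), with CYP83B1 at 0.87, CYP79B3 at 0.88, SOT16 at 0.68 and CYP79F1 at 0.81. No cellulose and xylan gene rose and 17 of 20 fell (camera adjusted p = 1.14e-05; adjusted p = 0.41 with an estimated correlation), with TBL29 at -0.69 and FLA11 at -0.54. Of 26 secondary wall transcription factors 18 fell (camera adjusted p = 5.74e-05; adjusted p = 0.24 with an estimated correlation), with MYB61 at -2.32, MYB4, a repressor of phenylpropanoid genes, at -1.49, MYB103 at -0.80 and BLH6 at -0.69. All 6 expansins, which loosen cell walls, fell (camera adjusted p = 2.29e-06; adjusted p = 0.065 with an estimated correlation), with EXPA8 at -2.82, EXPA1 at -1.53, EXPA10 at -1.497 and EXPA4 at -0.96. Of 14 starch degradation genes 11 fell, with PHS1 at -0.99, PHS2 at -0.88 and ISA3 at -0.97, and 3 rose, with BAM1 at 1.41 (camera adjusted p = 0.000285; adjusted p = 0.065 with an estimated correlation).

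In the clock list 11 of 16 genes fell and 5 rose (camera adjusted p = 0.000178; 0.048 with an estimated correlation), with FKF1 at -2.26. Of 6 cambium markers 5 fell (camera adjusted p = 0.00359; adjusted p = 0.30 with an estimated correlation), with the receptor PXY at -0.73, MOL1 at -0.87 and HB8 at -0.36. Of 7 epidermis markers 5 fell and 1 rose (camera adjusted p = 0.00188; adjusted p = 0.20 with an estimated correlation), with CER6 at -0.92, CER1 at -0.83, CER3 at -0.62 and PDF1 at 1.43. Of 5 vessel markers 3 fell (camera adjusted p = 0.0352; adjusted p = 0.41 with an estimated correlation), including the xylem peptidases XCP1 at -0.91 and XCP2 at -0.52. Of 31 photosynthesis genes 18 fell and 2 rose (camera adjusted p = 0.0345; adjusted p = 0.72 with an estimated correlation), with LHCB1.4 at -0.60, PSAD1 at -0.36, LHCB6 at -0.35 and FBA2 at 0.36. Of 13 sugar starvation genes 7 fell and 2 rose (camera adjusted p = 0.0130; adjusted p = 0.18 with an estimated correlation), with SEN1 at -0.89, TPS10 at -0.48, BCAT2 at -0.44 and BT2 at -0.52. The counts of these 13 lists were the same when adjusted over the list alone. Fitted on genes without opposite-strand overlap alone, photosynthesis genes (12 of 21 lower, 1 higher), sugar starvation genes (4 of 9 lower, 1 higher) and vessel markers (2 of 4 lower) were no longer called (camera adjusted p = 0.086, 0.16 and 0.26). In that fit the clock list had 7 of 12 genes lower and 5 higher (camera adjusted p = 0.00505; adjusted p = 0.081 with an estimated correlation).

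The monolignol list was not called in the libraries labelled gpt2-1 (camera adjusted p = 0.67), with 5 of 20 genes higher and 9 lower. CCR2, a cinnamoyl-CoA reductase, rose by 2.13 (SE 0.05) and PAL2 by 0.53, and CCOAOMT7 and C3H1 fell (-0.74 and -0.54). Of 14 laccases and peroxidases 4 rose and 8 fell (camera adjusted p = 0.92), with PRX71 at 1.75, PRX47 at 2.097, PRX4 at 1.84 and LAC12 at -0.90. Of 10 plastid translocators 3 rose and 4 fell (camera adjusted p = 0.35), with PPT2 at 1.67, GPT1 at -0.42 and XPT at -0.46 beside GPT2. On genes without overlap alone this list was called, with 3 of 6 higher and 2 lower (camera adjusted p = 0.00296; adjusted p = 0.080 with an estimated correlation). Its median log2 fold change was 0.05, GPT2 at 6.59 is a member, and the call was not tested without GPT2. Of 15 starch synthesis genes 2 rose and 7 fell (camera adjusted p = 0.22), with GBSS1 at 1.06, SBE2.1 at -0.80, SS4 at -0.40 and PGM1 at -0.37. Of 19 pentose phosphate genes 2 rose and 8 fell (camera adjusted p = 0.27), with PGL5 at 1.503, G6PD1 at -0.46, G6PD5 at -0.43 and G6PD6 at -0.25. Adjusted over the list alone, 9 laccases and peroxidases fell, and the counts of the other lists here were the same.

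Apart from GPT2, the largest rises in these libraries were AT1G32910 (log2 fold change 3.73, SE 0.14), the ethylene-response factor gene ABR1 (3.64, SE 0.07), AT5G19110 (3.55), AOC1 (3.38, SE 0.10), AT2G05950 (3.37), GSTU6 (3.24) and AT2G38240 (3.15). The largest falls were AT3G01345 (-9.15, SE 0.16, 0.17 ± 0.20 against 97.7 ± 8.42 CPM), AT5G37940 (-3.60, SE 0.31), PRR5, GRP7, ARGOS (-2.86), EXPA8, AT4G33980 (-2.72) and DREB1A (-2.39). AT3G01345 stood at 150 CPM without TMM scaling in Col-0 set 2.

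Plants with GPT2 under the 35S promoter were compared with their own wild type to ask what more GPT2 does in the stem. IRX15 (log2 fold change 1.21, SE 0.16, 594 ± 27.2 against 258 ± 32.5 CPM, n = 3), GUX1 (1.06, SE 0.15), GUX2 (1.23, SE 0.17) and TBL29 (1.203, SE 0.17), which act on xylan, rose. The peroxidase gene PRX64 (1.46, SE 0.16, 725 ± 55.5 against 264 ± 18.9 CPM) and the laccase gene LAC12 (1.37, SE 0.15) rose too. The flavonoid gene CHS, for chalcone synthase (-3.02, SE 0.28, 12.9 ± 3.14 against 108 ± 39.9 CPM) and MAM1 (-1.85, SE 0.16, 101 ± 7.62 against 364 ± 34.3 CPM), a gene of methionine-derived glucosinolates, fell. All of these passed the test in edgeR, and over all genes 462 of 18364 did, 258 higher and 204 lower, with 303 at least 2-fold.

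By list, 15 of 20 cellulose and xylan genes rose (camera adjusted p = 5.34e-33; 0.028 with an estimated correlation), and 20 when adjusted over the list alone. Of 26 secondary wall transcription factors 8 rose, and 14 adjusted over the list alone (camera adjusted p = 1.37e-15; adjusted p = 0.080 with an estimated correlation), with SND1, a master regulator of fibre walls, at 0.91, SND2 at 0.98, MYB61 at 1.53 and BLH6 at 0.80. Of 20 monolignol genes 5 rose, and 13 with 1 lower adjusted over the list alone (camera adjusted p = 7.45e-08; adjusted p = 0.17 with an estimated correlation), with PAL1 at 0.69, PAL2 at 0.74, C4H at 0.80 and C3H1 at 0.88. Of 11 laccases and peroxidases 5 rose, and 7 with 1 lower adjusted over the list alone (camera adjusted p = 1.99e-06; adjusted p = 0.15 with an estimated correlation), with LAC10 at 1.29 and LAC17 at 0.93. EXPA8 rose by 2.49, EXPA1 by 1.52 and EXPA4 by 0.64. Of 6 expansins these 3 rose, and 5 adjusted over the list alone (camera adjusted p = 5.13e-08; adjusted p = 0.11 with an estimated correlation). Of 5 vessel markers XCP2 and XCP1 rose, at 1.14 and 1.33, and 3 adjusted over the list alone (camera adjusted p = 0.000878; adjusted p = 0.17 with an estimated correlation). Of 22 salicylic acid genes DMR6 and PR2 rose, at 1.25 and 0.96, and 4 adjusted over the list alone (camera adjusted p = 0.00325; adjusted p = 0.17 with an estimated correlation). With the sample number as a block 19 cellulose and xylan, 13 wall transcription factor and 13 monolignol genes were higher. So were 6 laccases and peroxidases, 4 expansins, 3 vessel markers and 4 salicylic acid genes. A single monolignol gene was then lower.

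Other lists were lower in 35S GPT2. Of 22 flavonoid genes 9 fell, and 15 adjusted over the list alone (camera adjusted p = 1.30e-21; 0.048 with an estimated correlation), with LDOX at -2.03 and DFR at -2.01. Of 16 glucosinolate genes 6 fell, and 10 adjusted over the list alone (camera adjusted p = 2.23e-19; 0.022 with an estimated correlation), with CYP79F1 at -1.71, BCAT4 at -1.44 and CYP83A1 at -1.12. Of 12 phosphate starvation genes 3 fell, the acid phosphatase PAP17 (-2.48), PHO1 (-1.13) and GDPD1 (-0.95), and 5 adjusted over the list alone (camera adjusted p = 2.53e-09; 0.041 with an estimated correlation). Of 7 phloem markers the sucrose exporter SWEET11 fell (-2.01, SE 0.20), and no further member adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.17 with an estimated correlation). The starch lists were called lower with no single gene past the test. For starch synthesis the camera adjusted p was 9.61e-05 (adjusted p = 0.30 with an estimated correlation), with 3 of 15 genes lower adjusted over the list alone and GBSS1 at -1.39 (edgeR adjusted p = 0.051, and 0.012 with the block). For starch degradation it was 0.000208 (adjusted p = 0.20 with an estimated correlation), with 4 of 14 lower adjusted over the list alone and DPE2 at -0.66 (edgeR adjusted p = 0.062, and 0.0055 with the block). Shikimate and phenylalanine genes were called higher (camera adjusted p = 0.0106; adjusted p = 0.20 with an estimated correlation) with 0 of 20 past the test, 5 adjusted over the list alone, and EPSPS2 at 0.59 (edgeR adjusted p = 0.062, and 0.011 with the block). With the block, 10 glucosinolate, 4 phosphate starvation, 4 starch synthesis, 4 starch degradation and 2 jasmonate and ethylene genes were lower. Higher were 5 shikimate and phenylalanine genes. Of the pentose phosphate genes 1 was then higher and 2 were lower. Camera then also called photosynthesis genes (adjusted p = 0.0038 in place of 0.063, with 7 genes higher) and plastid translocators (0.021 in place of 0.052, with 1 gene higher) higher. The jasmonate and ethylene list was not called (camera adjusted p = 0.59), with 0 of 17 genes past the test and 2 lower adjusted over the list alone. Of 9 translocators GPT2 alone passed the test, also adjusted over the list alone. Fitted on genes without opposite-strand overlap alone, camera called the translocators higher (adjusted p = 0.0233; adjusted p = 0.18 with an estimated correlation). Of the 5 translocators in that fit 1 was higher, with a median of 0.16. GPT2, which the line overexpresses, is a member of this list, and neither call of it was tested without GPT2. Sugar starvation genes were called lower in that fit, with 3 of 8 past the test (adjusted p = 0.000329 in place of 0.12; adjusted p = 0.080 with an estimated correlation). The phosphate list, called by camera there too, had 2 of 9 lower (adjusted p = 0.059 with an estimated correlation). Of 18 pentose phosphate genes none passed (camera adjusted p = 0.37), with PGL1 at -0.65 (edgeR adjusted p = 0.054, and 0.022 with the block), and 1 was higher and 2 lower adjusted over the list alone.

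After GPT2, the largest rises in 35S GPT2 were AT2G20590 (log2 fold change 5.96, SE 0.27), the calmodulin-like gene CML41 (3.74, SE 0.45), AT5G37940 (3.29, SE 0.45), AT2G14900 (3.06), EXPA8, GASA4 (2.47) and DGR2 (2.41). The largest falls were AT5G44550 (-4.54, SE 0.50), AT4G38080 (-4.04), CYP86A1 (-3.87, SE 0.44), a fatty acid hydroxylase of suberin, ATSDI1 (-3.63), the sulfate transporter gene SULTR1;3 (-3.48), PELPK1 (-3.32), AT3G22620 (-3.23) and AT5G59080 (-3.08). The count of 462 genes was 1103 with the sample number as a block, and 106, 290 and 190 without 35S GPT2 replicates 1, 2 and 3 and 242 and 236 without Col-0 set 2 replicates 2 and 3. With the gene labels as deposited no gene passed in edgeR (350 at an unadjusted p under 0.05, and 129 with DESeq2), and 25 of 52 named genes lost their call when some single sample was left out. These were PAL1, PAL2, C4H, C3H1, LAC10, LAC17, GUX1, GUX2, SND1, SND2, MYB61, BLH6, EXPA1, EXPA4, XCP1, XCP2, PR2, DMR6, PAP17, PHO1, GDPD1, AT2G14900, GASA4, DGR2 and AT3G22620.

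**Figure D3:**
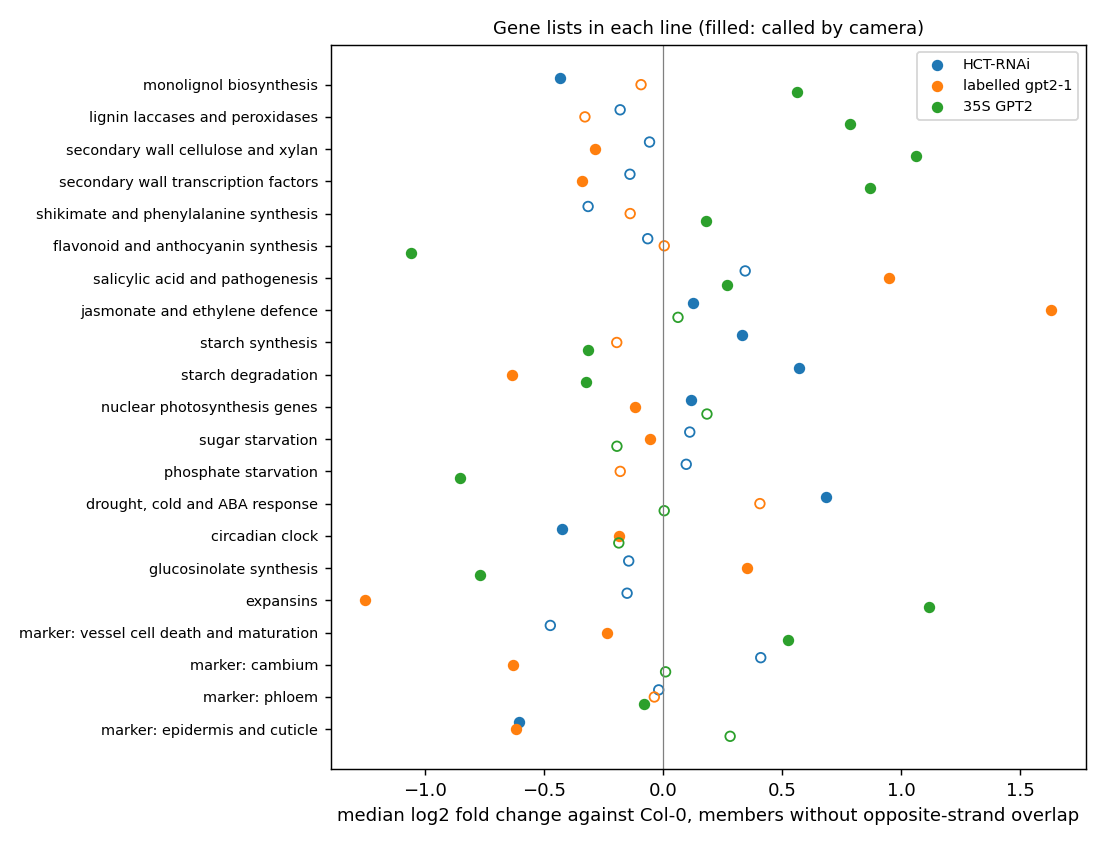
Median log2 fold change against wild type (horizontal axis) of the members of each gene list (vertical axis) without opposite-strand overlap, in HCT-RNAi, the libraries labelled gpt2-1 and 35S GPT2, with filled points for lists that camera called over all their members. Expansins lie at -1.25 in the libraries labelled gpt2-1 and 1.12 in 35S GPT2, and cellulose and xylan genes at -0.28 and 1.06.

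HCT-RNAi and the libraries labelled gpt2-1 were compared directly. Jasmonate and ethylene genes were lower in HCT-RNAi, with 17 of 23 lower and 5 higher and a median log2 difference of -1.44 (camera adjusted p = 1.37e-07; 0.017 with an estimated correlation). Starch degradation genes were higher, with 12 of 14 higher and 2 lower and a median of 1.14 (camera adjusted p = 6.39e-08; 0.020 with an estimated correlation). Adjusted over the list alone these counts were the same. On genes without opposite-strand overlap alone, 16 of 20 jasmonate and ethylene genes were lower and 3 higher (camera adjusted p = 2.675e-16; 0.00271 with an estimated correlation), and 11 of 12 starch degradation genes higher and 1 lower (camera adjusted p = 1.499e-11; 0.00957 with an estimated correlation). Camera called 9 further lists with the preset correlation and not with an estimated one. Higher in HCT-RNAi were photosynthesis (23 of 31 higher, 1 lower), starch synthesis (10 of 15, 1 lower), cambium markers (6 of 6) and drought (7 of 11, 4 lower), with camera adjusted p = 6.74e-05, 0.000405, 0.00355 and 0.00469 (adjusted p = 0.55, 0.10, 0.31 and 0.081 with an estimated correlation). Expansins (6 of 6), wall transcription factors (15 of 26, 5 lower) and cellulose and xylan (14 of 20, 1 lower) were also higher, with camera adjusted p = 0.0157, 0.0448 and 0.0465 (adjusted p = 0.24, 0.55 and 0.70 with an estimated correlation). Lower were salicylic acid (16 of 27 lower, 8 higher) and monolignol genes (16 of 20, 3 higher), with camera adjusted p = 0.00146 and 0.00365 (adjusted p = 0.15 and 0.55 with an estimated correlation). HCT itself is a member of the monolignol list, which was not tested without HCT. Adjusted over the list alone, 4 monolignol genes were higher and 2 cellulose and xylan genes lower, and the other counts were the same. Of these 9, drought was not called on genes without overlap alone (camera adjusted p = 0.12). Called there and not over all genes were cell wall integrity (5 of 7 lower in HCT-RNAi, 1 higher) and sugar starvation (7 of 9 higher, 2 lower). Their camera adjusted p was 0.031 and 0.019 (adjusted p = 0.21 and 0.18 with an estimated correlation). Over all genes 13674 of 20053 differed in edgeR, 7088 higher and 6586 lower in HCT-RNAi (4381 and 5200 among genes without overlap, but 4789 and 4752 when scaled and fitted on those alone). Across 14448 genes without overlap, which are not independent replicates, the fold changes of both lines had a Pearson correlation of 0.04 and a Spearman correlation of 0.09. Groups simulated without any effect against the same controls gave a correlation of 0.50. The covariance was 0.0245, against 0.0110 simulated. Of these genes 1259 were higher in both lines and 1461 lower in both, where independent lists would share 995.5 and 1148. The simulated groups shared 0, but they held no effect, so few genes could pass in either. This 0 thus does not measure what shared controls add where genes do change. In opposite directions, 793 were higher in HCT-RNAi and lower in the libraries labelled gpt2-1 and 1270 the other way, where independent lists would give 916.2 and 1247. With 3 control samples no split leaves 2 on each side, so part of the excess may come from the shared controls.

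The effects in 35S GPT2 and in the libraries labelled gpt2-1, each against its own wild type, differed for 4607 of 20645 genes in edgeR, 1924 higher and 2683 lower in 35S GPT2. This fit of all 15 samples shares 1 estimate of the spread, with a biological coefficient of variation of 0.125. It was 0.0402 in trial 1 and 0.234 in trial 2, so the spread of trial 2 may be understated here. In that fit 35S GPT2 had 2876 genes against its own wild type, in place of 462. Cellulose and xylan genes had the higher effect in 35S GPT2 in 18 of 20 cases (median difference 1.28, camera adjusted p = 7.10e-25; 0.00731 with an estimated correlation), and 20 adjusted over the list alone. Secondary wall transcription factors had it in 17 of 26, with 1 the other way (median 1.15, camera adjusted p = 4.22e-16; 0.017 with an estimated correlation), and in 22 adjusted over the list alone. Expansins had it in 5 of 6 (median 2.51, camera adjusted p = 5.68e-18; 0.00446 with an estimated correlation), and in 6 adjusted over the list alone. Glucosinolate genes had the lower effect in 35S GPT2 in 14 of 16 (median -1.04, camera adjusted p = 1.96e-19; 0.000307 with an estimated correlation), and 15 adjusted over the list alone. Jasmonate and ethylene genes had it in 12 of 23, with 1 the other way (median -1.34, camera adjusted p = 3.17e-08; 0.00976 with an estimated correlation), and in 13 adjusted over the list alone. Markers of vessels (3 of 5), epidermis (4 of 7) and cambium (3 of 6) also had the higher effect in 35S GPT2, with camera adjusted p = 0.00138, 0.00235 and 0.0158 (adjusted p = 0.12, 0.10 and 0.20 with an estimated correlation). So did monolignol genes (11 of 20, 2 the other way), laccases and peroxidases (7 of 14, 3 the other way) and clock genes (7 of 16, 5 the other way), with camera adjusted p = 0.000572, 0.00147 and 0.000624 (adjusted p = 0.33, 0.080 and 0.061 with an estimated correlation). Flavonoid (10 of 23) and phosphate starvation genes (6 of 13) had the lower effect, with camera adjusted p = 0.00226 and 0.00725 (adjusted p = 0.12 and 0.081 with an estimated correlation). The counts of these 8 further lists were the same adjusted over the list alone. With the sample number as a block, epidermis markers were called with an estimated correlation too (camera adjusted p = 0.0499). On genes without overlap alone the laccase, clock, flavonoid and phosphate lists were not called (camera adjusted p = 0.093, 0.12, 0.059 and 0.076). Called only there were cell wall integrity (5 of 7 lower, 1 higher) and shikimate and phenylalanine (6 of 13 higher, 1 lower). Their camera adjusted p was 0.019 and 0.025 (adjusted p = 0.18 and 0.28 with an estimated correlation). Across 12967 genes without overlap the fold changes of the lines had a Pearson correlation of -0.16, with GPT2 high in both. With the gene labels as deposited no gene differed in edgeR (9208 at an unadjusted p under 0.05, and 1535 with DESeq2).

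The wild type sets differed from each other in 10914 of 19373 genes in edgeR, 5533 higher and 5381 lower in set 2, with 6326 at least 2-fold. Of the 14007 tested genes without opposite-strand overlap 3494 were higher and 4243 lower, or 3769 and 3965 when scaled and fitted on those alone. Among genes named above, GRP7 stood at 6081 CPM in set 2, LOX3 at 7.55 CPM, LOX4 at 8.68 CPM and WRKY18 at 15.8 CPM, against 339 CPM, 593 CPM, 822 CPM and 274 CPM in set 1, all without TMM scaling. The labels do not say how the sets differ in growth or handling.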

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

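The tests of the gene label order, of opposite-strand overlap and of label swaps, and the correlation between the GPT2 lines, were chosen after the results had been seen, while the test of the genes beside GPT2 and the counts over other splits of the samples were planned. A difference between lines marked each of the following results. HCT-RNAi and the libraries labelled gpt2-1 differed in 13674 genes, and no gene passed in any of the other 9 splits of these samples, but 10 splits are too few for a share under 0.05. The effects in 35S GPT2 and in the libraries labelled gpt2-1 differed in 4607 genes. Of 100 splits 1, the real one, gave as many, with 3190 as the highest of the others. Of those others, 8 kept the real grouping of trial 1 and gave 1739 to 3190 genes. In 6 that kept the grouping of trial 2 it was 199 to 384, and 85 kept neither and gave 0. Where a split does not keep a trial's grouping, it removes that line's effect. The splits thus set the count against no effect in a line. They cannot exclude chance for a difference between 2 effects that are both present, and took no account of the trial 2 pairs. Between HCT-RNAi and the libraries labelled gpt2-1 the median log2 difference was -1.44 for jasmonate and ethylene genes and 1.14 for starch degradation genes. The effect in 35S GPT2 minus that in the libraries labelled gpt2-1 had a median of 1.28 for cellulose and xylan, 1.15 for secondary wall transcription factors, -1.34 for jasmonate and ethylene, -1.04 for glucosinolates and 2.51 for expansins.

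For the comparisons with wild type, 10 splits of 3 against 3 cannot give a share under 0.05. The real split gave 11167, 10677 and 462 genes in HCT-RNAi, the libraries labelled gpt2-1 and 35S GPT2, and the highest other split gave 0 genes in each. Of the 10 splits in trial 2, 4 parted all 3 pairs of the same sample number, the real one among them, and 6 parted 1 pair. For the Col-0 sets these values were 10914 and 0. In each of these comparisons 1 of 10 splits, the real one, gave as many genes. Of gene lists the real split called 8, 13 and 14 and the highest other split 9 in each line, and 5, 1 and 1 of the 10 splits gave as many. The number of lists called in HCT-RNAi is thus not set apart from that of other splits.

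The counts of 5 trial 2 tables did not follow their gene labels. Other plants or tissue under correct labels would still share abundant genes with Col-0 set 1, and the highest correlation of 0.1117 as labelled argues against that. Values left in the row order of the first 35S GPT2 table may be the source, since reading them in that order gave a correlation of at least 0.8406 in every full window of 1000 rows. How the order came about stays open, and no other biological explanation was tested. The equal GPT2 counts in both Col-0 sets as deposited are not explained by that order. In 35S GPT2 replicate 3 the row labelled GPT2 held 3729 counts as deposited. Read in the other order they fall on PGD1, at 297.4 CPM without TMM scaling. PGD1 stood at 54.96 and 51.73 CPM in replicates 1 and 2, so this value stands out as well, and its source was not tested.

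Genes under an opposite-strand exon were higher in HCT-RNAi than in Col-0 set 1. An effect of HCT silencing on them as a set is argued against by Col-0 set 2, also wild type, which was higher than Col-0 set 1 by a median of 4.494 at 75 to 100% overlap. For single genes such an effect stays open. MYC2, for 1, stood at 69.89 CPM without TMM scaling in Col-0 set 2 and at 1424 CPM in HCT-RNAi. Reads counted with strand in some tables and without it in others may be the source, since the median difference was 4.343 at that overlap and -0.05123 without overlap. The counting settings behind each table stay unknown, and the 24 genes more than 20-fold lower in HCT-RNAi, 22 of which were as low in Col-0 set 2, have a median overlap of 0 and are not covered by it.

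GPT2 was high in the libraries labelled gpt2-1. A swap with 35S GPT2 is argued against by the lowest GPT2 level there, 213.1 CPM without TMM scaling, and a swap with HCT-RNAi by HCT, which was lower in HCT-RNAi than in the libraries labelled gpt2-1 by a log2 value of -1.174 (SE 0.05). Plants that overexpress GPT2 under a gpt2-1 label stay open, because the correlation of -0.1562 with the effects of 35S GPT2 also carries the difference between trials. Transcription spreading over the region stays open as well: of 3 tested genes starting within 10 kb of GPT2, BGLU46 had the largest log2 fold change, 0.9953 (SE 0.06), which lies under the planned bound of 1 by less than its SE, so the verdict on this test was changed to undecided after its value had been seen. BGLU45, which lies between GPT2 and BGLU46, was at 0.10 (SE 0.04), and AT1G61795, on the other side, at 0.28 (SE 0.14). None of the 3 reached the rise predicted for spreading. A transcript started or cut short by an insertion in GPT2 could not be tested on counts per gene, and an effect of the mutation itself stays open as untested.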

How the results depend on the processing

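The gene labels as deposited, the fit on genes without opposite-strand overlap and the block in list tests between lines were alternatives chosen after seeing the data, and the others were planned. At an absolute log2 fold change of at least 1 the counts were 2058 in HCT-RNAi, 2033 in the libraries labelled gpt2-1, 303 in 35S GPT2, 3929 between HCT-RNAi and the libraries labelled gpt2-1, 2358 for the difference of the GPT2 lines' effects and 6326 between the Col-0 sets, fewer by construction. At an adjusted p under 0.01 they were 151 in 35S GPT2 and 2866 for the difference of effects, also by construction. With all 15 samples in 1 fit, which share 1 estimate of the spread (biological coefficient of variation 0.125, against 0.0402 and 0.234 in the trials), they were 4726, 4894 and 2876 in the 3 lines and 8485 between HCT-RNAi and the libraries labelled gpt2-1. On genes without overlap alone HCT-RNAi had 7392, with fewer genes tested. DESeq2 gave 918 in 35S GPT2, and the cause was not tested.

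With the gene labels as deposited 35S GPT2 and the difference of effects had 0 genes in edgeR (350 and 9208 at an unadjusted p under 0.05, 129 and 1535 with DESeq2), and the Col-0 sets had 24895. Camera called 12 lists in 35S GPT2 with these labels, against 14. Counts of other rows stood under the members' names there, so these 12 calls lend the lists no support. They show that camera at the preset correlation calls lists on such counts too. Whether the same lists were called in the same direction was not compared. The log2 fold change in 35S GPT2 then turned for EXPA8 (-0.80), AT5G44550 (0.17), DPE2 (1.54), PGL1 (1.94), GUX2 (-0.81), MYB61 (-0.42), DFR (3.33), BCAT4 (1.31) and CYP83A1 (2.74), since another row's counts stood under these names.

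With the correlation estimated per list, camera called 2, 2 and 4 lists in HCT-RNAi, the libraries labelled gpt2-1 and 35S GPT2, and fry, which does not compare a list with other genes, called 22, 21 and 16. Leaving out 1 sample at a time gave 10193 to 11379 genes in HCT-RNAi, 9684 to 10668 in the libraries labelled gpt2-1, 106 to 673 in 35S GPT2, 13038 to 14043 between the first 2, 3642 to 5919 for the difference of effects and 8597 to 14242 between the Col-0 sets, and 7 to 9, 11 to 13 and 12 to 15 lists. The lowest count in 35S GPT2 came without its replicate 1 and the highest without Col-0 set 2 replicate 1. Genes taken by the naming rule, not all printed here, held their call in all of these fits in 66 of 66 cases in HCT-RNAi. They did so in 86 of 87 cases in the libraries labelled gpt2-1 and 27 of 52 in 35S GPT2. The exception in the libraries labelled gpt2-1 was the vessel marker RNS3 (log2 fold change -0.24), which passed in 6 of 9 fits. The counts with DESeq2 size factors and with no filter on low counts stayed within 1.5 times the counts reported.

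With the replicate block, 35S GPT2 had 1103 genes, 617 higher and 486 lower, and 16 lists. In trial 1 samples share only a number (correlations of -0.10 to 0.02 between samples with the same number), and the replicate block gave 10945, 10438 and 13527 genes and 7 and 12 lists, with camera adjusted p = 0.071 for epidermis markers in HCT-RNAi and 0.071 for vessel markers in the libraries labelled gpt2-1. It gave 6432 genes for the difference of effects and 9658 between the Col-0 sets. Beyond the values given with the 35S GPT2 results, it changed no other list call in the comparisons with wild type. Between HCT-RNAi and the libraries labelled gpt2-1 it gave a camera adjusted p of 0.029 in place of 0.14 for cell division and 0.057 in place of 0.0047 for drought, and for the difference of effects 0.0042 in place of 0.059 for photosynthesis (adjusted p = 0.38, 0.25 and 0.70 with an estimated correlation), with the other calls of these 55 tests at the preset correlation as before. At the estimated correlation the block called epidermis markers for the difference of effects (camera adjusted p = 0.0499 in place of 0.10). It changed no other of these calls. Fewest simulated changes of 1 on the log2 scale, 41%, were recovered for 35S GPT2. Trial 2 holds the shallowest sample, with 3827816 counts, and the wider spread, and these were not separated.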

Other observations

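The clock test was planned before its values were seen, on genes chosen after the clock list had been seen, and the list tests and comparisons between lines were planned, except for the fits on genes without opposite-strand overlap. Lists outside the lignin and wall themes held further changes. Of 8 cell division genes 7 were higher in HCT-RNAi and 3 lower in the libraries labelled gpt2-1, and none passed in 35S GPT2, with camera adjusted p = 0.34, 0.35 and 0.36, so the list was not called in any line over all genes. Of 6 cambium markers 4 were higher in HCT-RNAi (camera adjusted p = 0.22), or 5 of 6 when fitted on genes without opposite-strand overlap alone (camera adjusted p = 0.0104; adjusted p = 0.29 with an estimated correlation), and the list was higher in HCT-RNAi than in the libraries labelled gpt2-1 for 6 of 6 genes (camera adjusted p = 0.00355; adjusted p = 0.31 with an estimated correlation). Of 10 cell wall integrity genes 3 were higher and 3 lower in HCT-RNAi, 6 higher and 3 lower in the libraries labelled gpt2-1, and none passed in 35S GPT2 (camera adjusted p = 0.097, 0.079 and 0.44). Fitted on genes without overlap alone it was called in the libraries labelled gpt2-1, with 6 of 7 higher and 1 lower (camera adjusted p = 0.00205; adjusted p = 0.080 with an estimated correlation). Of 10 senescence genes 2 were higher and 7 lower in HCT-RNAi, 2 higher and 4 lower in the libraries labelled gpt2-1, and 0 of 9 passed in 35S GPT2 (camera adjusted p = 0.99, 0.36 and 0.39). Adjusted over the list alone 5 cambium markers were higher in HCT-RNAi, and the other counts here were the same.

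Few markers of other organs had enough counts to be tested. Of 12 flower and anther markers 5 were tested in trial 1, with 2 higher in HCT-RNAi and 1 higher in the libraries labelled gpt2-1 (camera adjusted p = 0.85 and 0.99). Of 10 seed markers 4 were tested, for the difference of the GPT2 lines' effects alone, and none passed (camera adjusted p = 0.66). AT5G37940 was among the largest changes of both GPT2 lines and went opposite ways, with log2 fold changes of -3.60 in the libraries labelled gpt2-1 and 3.29 in 35S GPT2, and the difference of 6.77 (SE 0.58) passed the test in edgeR (adjusted p = 3.23e-07).

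Clock genes moved in opposite directions in the libraries labelled gpt2-1, with LHY higher and PRR5, GRP7 and FKF1 lower. A harvest at another time of day may lie behind this, and it was tested on 6 dawn genes and 2 evening genes outside the clock list. The dawn genes had a median log2 fold change of -0.1757, below 0 and so against the prediction, but they ranged from -0.83 for RVE7 to 0.84 for LNK2, and such a median decides nothing. The verdict on this test was changed to undecided for that reason after its value had been seen. The evening genes PRR3 and GRP8 had a median of -1.53, as the prediction asked, and a harvest time and an effect of the line cannot be told apart with these values. In HCT-RNAi, where the clock list was called too, all 6 dawn genes fell and passed the test in edgeR. They ranged from -0.21 for RVE7 (adjusted p = 0.0034) to -1.375 for LNK3, with a median of -0.54. Of the evening genes GRP8 rose by 0.37 (edgeR adjusted p = 9.57e-08) and PRR3 stood at -0.005 (edgeR adjusted p = 0.97). No prediction was set for HCT-RNAi, and harvest time and an effect of the line cannot be told apart there either.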
